A study of Mus musculus with 6 samples.

How the data were processed

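Total RNA of 6 cultures was measured on Illumina 1-colour bead arrays after biotin labelling, with 3 arrays of i2PS cells and 3 of E14TG2A cells. Per the labels, both lines were first kept on mouse embryonic fibroblast feeders in DMEM with LIF and then passaged 3 times on gelatin to remove the feeders. The labels call the 3 cultures of each line biological replicates.

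The deposited table of linear probe intensity values holds 45281 probes per array, and GenomeStudio is named as its source in the submitters' processing notes, where no version or setting was given. These intensities were normalized neither between arrays nor for background, since their medians ran from 88.3 to 103.3 and no signal lay below 72.1. Beside each signal the authors deposited a detection p-value, which ranks the probe among that array's negative controls in steps of 1 in 936. A further table of the authors' processed intensity values holds the same arrays after quantile normalization on the linear scale, with medians of 96.7 on each array. Its scale and form were read from the values, because each column had a rank correlation of 1 with its own array and the sorted values lay within 0.167 of the mean quantiles. It was not centred, and it was used only as an alternative.

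Signals were corrected and normalized with limma 3.58.1 in R 4.3.3. The neqc method took the background from the detection p-values, added an offset of 16, applied quantile normalization and gave log2 values. A probe was kept if its detection p was under 0.01 on all 3 arrays of at least 1 line and if it carried 1 gene symbol. Probe names came from the platform annotation of GEO, updated with a RefSeq gene table of GRCm38.p6. Of the probes, 34885 carried 1 symbol, 18 carried several and 10378 were unlisted, and the last groups were kept out of the gene tests. A gene number matched 34807 of the named probes to the gene table, an accession matched 11, and 67 kept the platform symbol. Where several probes of a gene were kept, the probe with the highest mean over the 6 arrays stood for it. Among 1253 genes past the threshold with more than 1 kept probe, 1106 had every other probe on the same side, and 40 had another probe past the threshold in the opposite direction.

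The lines were compared with lmFit and eBayes of limma and a Benjamini-Hochberg threshold of 0.05. All log2 differences are i2PS minus E14TG2A, each with its SE and 3 arrays per line, and all adjusted p-values of genes are from this limma fit. A gene was held within 2-fold when its 95% confidence interval lay wholly between -1 and 1. For a gene that was detected on no array of a line, the fold is given as at least the bright line's mean over the dim line's mean of the lowest detected signal per array, or of the gene's own signal where that was higher. Such a bound holds for the main background correction only. Il4i1, Zscan4c, Slc22a18, Bgn, Sox9, Tfpi and Hprt were detected on 2 of 3 E14TG2A arrays, Sall2 on 2 and Cd74 on 1 of the i2PS arrays, so that their differences rest in part on signals near background. The number of arrays limits the precision of every value.

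Before the data were examined, 28 gene lists, the rule for naming genes, the design and the alternatives were fixed. Lists with at least 5 tested members, 19 in all, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which tests the list's own genes without setting them against others. Chromosomes were tested in the same way. No list call of the preset test held with the estimated correlation. This was so even for germline (-0.011), endothelial (-0.044) and trophectoderm genes (-0.041), whose estimated correlations lay below the preset. A call lost there thus does not show that the members of a list vary together. The genes named were the reprogramming factors, Nanog, Hprt, Xist and the members of lists of at most 6, the 6 genes with the largest rise and the 6 with the largest fall, up to 2 members with the largest rise and fall of each list, and 3 genes of the chromosome with the largest median shift. The 6 largest rises and the 6 largest falls were taken among genes past the threshold whose lines did not overlap. Clone and predicted gene names were left out there. Genes named outside this rule were chosen after their values were seen. They are marked where they stand or belong to a list named in the same paragraph. Profiles were compared by Pearson correlation across genes, with an exact one-sided permutation of the 6 arrays, whose smallest p is 0.1.

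The alternatives were normexp with an offset of 50, no background correction, equal medians or cyclic loess in place of quantile normalization, the authors' table, 3 other filters on dim probes, the mean of a gene's probes, a variance trend with robust moderation, array weights, the replicate number as a block, and each array left out in turn. A slide block was planned and not run, because no slide was given in the sources used here.

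The fit was tested on simulated signals of this comparison with 8256 genes. It called 93.3% of 60 genes changed by 2 (log2), 81.0% of 63 changed by 1 and 21.5% of 65 changed by 0.5, and 8.11% of its calls were false. A planted fall of 60 neighbouring genes was found at its true first and last gene. The simulation held few changed genes and gave 185 calls, against 3781 in the data. Its rates therefore do not carry over to the real comparison. In the simulation, genes below 2-fold change were called incompletely.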

Results

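Gene expression was measured in i2PS cells, a pluripotent line that was reprogrammed in vivo from BALB/c liver, and in E14TG2A, an embryonic stem cell line of the 129 strain that served as the reference. The comparison asks how far the expression profile of the in vivo induced line matches that of this embryonic stem cell line. Strain, tissue of origin and reprogramming history all differ between the lines, so that none of them can be separated from the others. Each line had 3 arrays. The SEs and p-values measure the spread between cultures of these lines, and they do not extend to other induced or embryonic stem cell lines. Mean signal per array was 340 to 357 in i2PS and 359 and 403 in E14TG2A replicates 2 and 3, but 228 in E14TG2A replicate 1, where 13994 probes were detected against 14953 to 15922 elsewhere.

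The reprogramming factors Pou5f1, Sox2 and Klf4 did not pass the test between the lines. Pou5f1 differed by 0.10 ± 0.13 (log2, SE, n = 3 per line; limma adjusted p = 0.54) and Sox2 by -0.25 ± 0.12 (adjusted p = 0.11). Both intervals, from -0.19 to 0.40 for Pou5f1 and from -0.52 to 0.01 for Sox2, excluded a 2-fold difference. Klf4 differed by 0.07 ± 0.25 and Nanog by 0.53 ± 0.22 (adjusted p = 0.84 and 0.086), and without the dim array E14TG2A replicate 1 they passed at 0.42 and 0.76 (adjusted p = 0.0097 and 0.0091). With all arrays Nanog also passed with normexp (0.0419), the mean of its probes (0.0290), array weights (0.0057) and the replicate number as a block (0.0106). Myc was detected on no array with either of its probes.

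**Figure D1:**
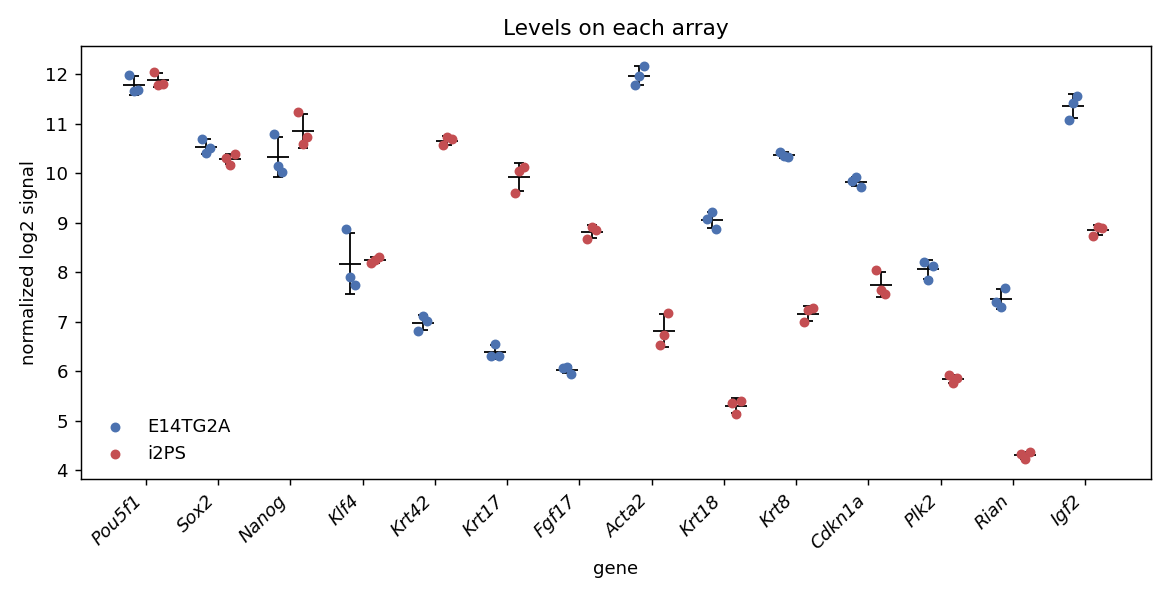
Normalized log2 signal of 14 genes on each of the 6 arrays; points are arrays, and the bars give the mean and SD of the 3 arrays of a line. The lines overlap for Pou5f1, but not for Krt42, at a mean of 10.66 in i2PS and 6.99 in E14TG2A, nor for Acta2, at 6.82 and 11.98.

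Of 31 tested genes of core and naive pluripotency, 8 were higher in i2PS, 4 were lower and 19 did not pass. Adjusted over the list alone, the counts were again 8 and 4. The list as a whole did not differ from other genes (camera adjusted p = 0.51), and 26 of its members were held within 2-fold. Gbx2, a target of LIF signalling, rose by 1.95 ± 0.14, and Nr5a2, a nuclear receptor that can activate Pou5f1, rose by 0.92 ± 0.14. Dppa3, which is expressed in the oocyte and germ line, fell 2.83-fold (adjusted p = 3.4e-05). Pecam1 differed by -1.16 ± 0.11, but another of its probes passed in the opposite direction.

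Primed epiblast genes were mostly lower in i2PS. Of 16 tested, 10 fell and 3 rose (camera adjusted p = 0.0175; adjusted p = 0.36 with an estimated correlation). Krt18, an epithelial keratin, fell by 3.76 ± 0.13 and Sall2 fell by 1.92 ± 0.22, whereas Etv4, a transcription factor downstream of FGF, rose by 2.16 ± 0.15 and Tcf15 by 1.51 ± 0.15. The list's call ended without E14TG2A replicate 1 (adjusted p = 0.0514) and among genes detected on all 6 arrays (adjusted p = 0.35). Of 3 tested genes expressed in 2-cell-like cells, Zscan4c was higher by 1.28 ± 0.27, and Dppa3 and Ddit4l, the latter by -2.43 ± 0.15, were lower.

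Leaving out clone and predicted names and genes whose lines overlapped, the genes with the largest differences were of several kinds. Acta2, smooth muscle actin, fell 35.7-fold (log2 -5.16 ± 0.17, adjusted p = 5.0e-07), and all 3 of its other kept probes were lower as well. Krt18 fell 13.6-fold, Kif1a, a kinesin of neurons, 12.1-fold and Krt8, the partner of Krt18, 9.19-fold. Across the alternatives their log2 differences were -3.82 to -2.40, -3.69 to -2.69 and -3.26 to -2.66. Acta1 and Pmp22 were not detected on any i2PS array and were at least 6.48-fold and 6.60-fold lower. Across the alternatives their log2 differences were -3.52 to -1.56 and -3.33 to -1.54. In the other direction, the keratins Krt42 and Krt17 rose 12.8-fold and 11.5-fold, Fgf17 6.90-fold and Itpk1 6.21-fold. Il4i1, which was detected on 2 of 3 E14TG2A arrays, rose by 2.56 ± 0.28, with 1.37 to 2.78 across the alternatives. Fbln2, a matrix protein, was not detected in E14TG2A and was at least 5.49-fold higher in i2PS.

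Over all 8651 tested genes, 3781 passed the threshold, 2017 higher and 1764 lower in i2PS. At least 2-fold were 273 higher and 402 lower, 675 in all. A 2-fold difference was excluded for 6990 genes (80.8%), of which 2207 also passed the threshold, and 87 genes were neither. The lines did not overlap in 55.8% of genes, where chance gives 10%. Across genes, which are not independent replicates, the correlation between arrays averaged 0.956 between lines and 0.991 within lines. This difference of -0.0355 had an exact permutation p of 0.1, the smallest that 10 splits allow. The first principal component held 77.4% of the variance and separated the lines, and the second, at 12.6%, set E14TG2A replicate 1 apart. With equal medians in place of quantile normalization only 634 genes passed. All 634 were at least 2-fold, against 675 such genes in the main fit. Of these 2-fold differences 56.3% were then higher in i2PS, against 40.4%.

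**Figure D2:**
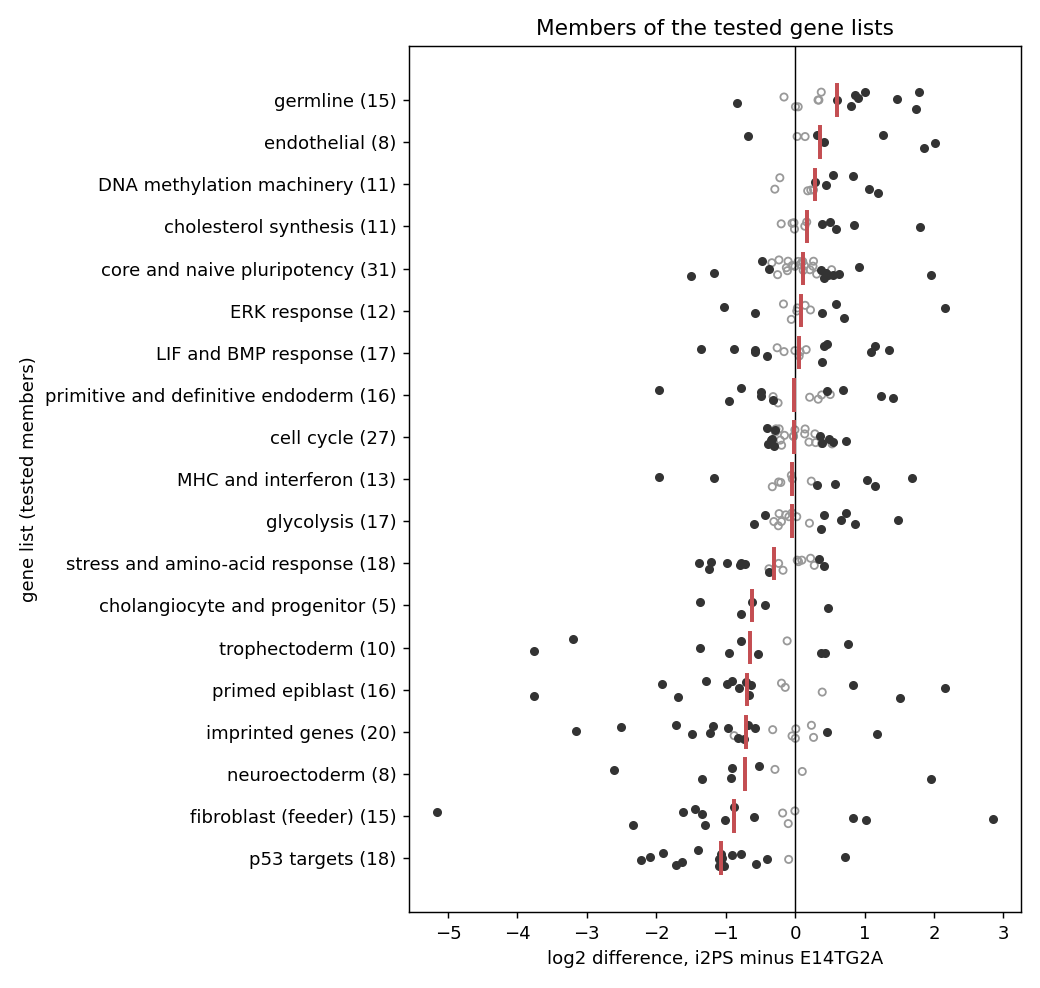
The log2 difference of each tested member of the 19 tested lists, with the number of members in parentheses; filled points passed the adjusted p threshold of 0.05, open points did not, and the red bar is the list's median. The medians run from -1.07 for p53 targets to 0.60 for germline genes.

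Targets of p53, the transcription factor that answers DNA damage, had the largest median shift of the 19 lists tested with camera. Of 18 tested, 16 fell, 1 rose and 1 did not pass, with a median of -1.07 (camera adjusted p = 5.5e-08; adjusted p = 0.19 with an estimated correlation). Cdkn1a, an inhibitor of the cell cycle, fell by 2.08 ± 0.14, and Plk2, a polo-like kinase, fell by 2.21 ± 0.13. Sesn1 rose by 0.71 ± 0.12. Stress and amino-acid response genes, which share Sesn2 with this list, fell in 8 and rose in 2 of 18 cases (camera adjusted p = 0.042; adjusted p = 0.39 with an estimated correlation), among them Hspa1a, at least 2.01-fold lower, and Ddit4, by -1.23 ± 0.11. That call ended without E14TG2A replicate 1 (adjusted p = 0.0525), E14TG2A replicate 3 (0.0528), i2PS replicate 2 (0.0507) or i2PS replicate 3 (0.0527), and among genes detected on all 6 arrays (0.106). Its rises, Xbp1 at 0.42 ± 0.12 and Trib3 at 0.34 ± 0.12, were weak. Xbp1 no longer passed without i2PS replicate 1 (0.0815) or i2PS replicate 3 (0.0973), and Trib3 without any array other than E14TG2A replicate 1 (0.0566 to 0.155). Cell cycle genes rose in 5 and fell in 6 of 27 cases (camera adjusted p = 0.97), with Ccne2 higher by 0.74 ± 0.15 and Ccnd3 by 0.54 ± 0.12. Adjusted over the list alone, 4 rose and 3 fell. Mcm2, at -0.41 ± 0.11, did not pass without i2PS replicate 2 (0.0542) or i2PS replicate 3 (0.0520). Mcm3, at -0.39 ± 0.12, did not pass without E14TG2A replicate 2 (0.0549), i2PS replicate 2 (0.116) or i2PS replicate 3 (0.0911).

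Imprinted genes were lower in 11 and higher in 2 of 20 cases, with a median of -0.71 (camera adjusted p = 0.0031; adjusted p = 0.24 with an estimated correlation). Igf2, a paternally expressed growth factor, fell by 2.50 ± 0.14. From the Dlk1-Dio3 region, 3 genes were tested and all 3 fell. The maternally expressed RNAs Rian and Meg3 were not detected on any i2PS array and were at least 5.64-fold and 1.72-fold lower, and Dlk1, which is expressed from the paternal allele, fell by 0.96 ± 0.17 (adjusted p = 0.0021). The region lies in a part of chromosome 12 where neighbouring genes were lower too, and without the shifted parts of that chromosome the list had a median of -0.58 (camera adjusted p = 0.0255). Without the filter on dim probes, where 34 members entered, the median was -0.14 (adjusted p = 9.8e-04). Slc22a18 rose by 1.18 ± 0.14. Mest was higher by 0.45 ± 0.12, a call that ended without i2PS replicate 3 (adjusted p = 0.0699). Rtl1 and Dio3 were detected on 1 array each and were not tested.

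Germline genes were higher in 8 and lower in 1 of 15 cases (camera adjusted p = 0.0060; adjusted p = 0.23 with an estimated correlation), and 9 were higher when adjusted over the list alone. The X-linked homeobox genes Rhox6, at least 2.78-fold, and Rhox9, by 1.75 ± 0.16, rose most, and Taf7l was lower, at -0.83 ± 0.19. The list's call ended among genes detected on all 6 arrays (adjusted p = 0.087). Genes of DNA methylation and its partners were higher in 6 of 11 cases and lower in 0 (camera adjusted p = 0.0216; adjusted p = 0.27 with an estimated correlation), and 7 were higher when adjusted over the list alone. Tet1, which oxidises methylcytosine, rose by 1.07 ± 0.11, and Ehmt2, a histone methyltransferase, by 1.19 ± 0.12.

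Markers of the liver of origin were scarce on all arrays. Of 33 hepatocyte genes on the array, 4 were detected well enough to be tested, and Foxa3, a liver and endoderm factor, was higher by 0.47 ± 0.12 in i2PS. The other 3 did not pass, and Alb and Afp, the main serum proteins of adult and fetal hepatocytes, were detected on no array. Of 16 genes of liver macrophages and blood, only Cd74 was tested, at -0.27 ± 0.16 (adjusted p = 0.21). Of 5 cholangiocyte genes 4 were lower and 1 was higher (camera adjusted p = 0.055; adjusted p = 0.25 with an estimated correlation), with Krt19 at least 2.10-fold and Krt7 at least 1.60-fold lower. The list passed without E14TG2A replicate 2 (0.0381) or i2PS replicate 2 (0.0449) and with equal medians (0.0397). Its rise was Sox9, at 0.47 ± 0.15, which did not pass without E14TG2A replicate 2 (0.0897), E14TG2A replicate 3 (0.0576), i2PS replicate 2 (0.104) or i2PS replicate 3 (0.130).

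Fibroblast genes, which would mark feeder cells, were lower in i2PS in 9 and higher in 3 of 15 cases, with a median of -0.89 (camera adjusted p = 0.0139; adjusted p = 0.25 with an estimated correlation). Without the filter on dim probes, where 31 members entered, the median was -0.06 (adjusted p = 0.0249). Beside Acta2, the actin-binding Tagln was at least 3.47-fold lower, whereas Fbln2 and Bgn, the latter by 1.02 ± 0.26, were higher. Of 8 abundant matrix genes of fibroblasts, Col1a1 was detected on 2 E14TG2A arrays, Dcn on 1 i2PS array and the other 6 on none. Endothelial genes were higher in 5 and lower in 1 of 8 cases (camera adjusted p = 0.042; adjusted p = 0.25 with an estimated correlation). Robo4 and Esam were detected only in i2PS and were at least 3.31-fold and 3.05-fold higher there, and Eng was lower, at -0.67 ± 0.15. The endothelial call ended without E14TG2A replicate 1 (adjusted p = 0.0546), E14TG2A replicate 3 (0.0528) or i2PS replicate 1 (0.0579), with array weights (0.0623) and with the replicate number as a block (0.0510). Among genes detected on all 6 arrays, where 5 members remained, the median was 0.14 (adjusted p = 0.67).

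Among the germ layers, neuroectoderm genes were lower in 5 and higher in 1 of 8 cases (camera adjusted p = 0.042; adjusted p = 0.35 with an estimated correlation), with Nes, an intermediate filament of neural progenitors, at -2.61 ± 0.21 and Sox11 at -1.34 ± 0.11. That call ended without E14TG2A replicate 1 (adjusted p = 0.0733), E14TG2A replicate 3 (0.0528) or i2PS replicate 1 (0.0703), with array weights (0.0724), with the replicate number as a block (0.0510) and among genes detected on all 6 arrays (0.0867). Trophectoderm genes, which include Krt8 and Krt18 and, among those higher, Tead4 (0.76 ± 0.15) and Tfap2c (0.44 ± 0.11), were lower in 6 and higher in 3 of 10 cases (camera adjusted p = 0.0343; adjusted p = 0.25 with an estimated correlation), and their call ended without E14TG2A replicate 1 (0.0546) or i2PS replicate 1 (0.0726). Their median moved from -0.66 to -0.38 without i2PS replicate 1, to -0.11 among genes detected on all 6 arrays (adjusted p = 0.31) and to -0.06 without the filter on dim probes (0.0590). Endoderm genes rose in 4 and fell in 6 of 16 cases (camera adjusted p = 0.82), with Lama1 at 1.42 ± 0.11, Tfpi at 1.23 ± 0.15, Lrp2 at -1.96 ± 0.12 and Sparc at -0.95 ± 0.10. Of 4 mesoderm genes 1 rose, Bmp4, by 1.05 ± 0.11. The endothelial, neuroectoderm, trophectoderm and stress calls also ended without background correction, at adjusted p from 0.0525 to 0.0543.

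In the LIF and BMP list 6 of 17 genes rose and 5 fell (camera adjusted p = 0.82), with Socs3, a feedback inhibitor of LIF signalling, at 1.35 ± 0.12 Bcl3 at 1.14 ± 0.12 and Id2, a target of BMP, at -1.35 ± 0.19. Junb, at -0.88 ± 0.24, did not pass without i2PS replicate 2 (0.0510) or i2PS replicate 3 (0.0515). In the ERK list 4 of 12 rose and 2 fell (adjusted p = 0.49), with Spred1 at 0.71 ± 0.13, Phlda1 at -1.03 ± 0.21 and Ier3 at -0.58 ± 0.15. Glycolysis genes rose in 6 and fell in 2 of 17 cases (adjusted p = 0.62), with a median of -0.04 but a mean of 0.15, and Pdk1 rose by 1.49 ± 0.11 and Eno3 by 0.86 ± 0.10, while Eno2 was at -0.60 ± 0.13. Slc2a3, at -0.44 ± 0.12, did not pass without i2PS replicate 1 (0.0563) or i2PS replicate 3 (0.0727). Cholesterol synthesis genes rose in 5 and fell in 0 of 11 cases (adjusted p = 0.086; adjusted p = 0.27 with an estimated correlation), led by Fdps, at 1.80 ± 0.10, and Mvd, at 0.85 ± 0.12. That list passed with equal medians (0.0477), without the filter on dim probes (0.0249) and with array weights (0.0480). In the MHC and interferon list 5 of 13 rose and 2 fell (adjusted p = 0.82), or 5 and 3 when adjusted over the list alone. Ifi27 and Ifit2 were at least 2.26-fold and 1.59-fold higher. The falls were the class I genes H2-T23, at -1.95 ± 0.12, and H2-D1, at -1.17 ± 0.12, whose haplotypes can differ between strains.

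Sex-linked and line-specific transcripts were checked last. Eif2s3y, on the Y chromosome, was detected on all 6 arrays and was higher in i2PS by 0.74 ± 0.13. Of the other Y-linked genes, Kdm5d, Usp9y and Zfy1 were detected on no array and Uty on 1, while Xist was detected on no array with any of its 4 probes. Of 2 tested genes of X inactivation, Tsix did not pass (-0.02 ± 0.13), and Rlim was at -0.41 ± 0.14 (adjusted p = 0.038), a call that ended without any array other than E14TG2A replicate 1 (adjusted p from 0.077 to 0.115). Hprt, which is known to be deficient in E14TG2A, was higher in i2PS by 0.59 ± 0.17 (adjusted p = 0.021), but 1 of its 3 probes was detected, with signals of 95.1 to 152.0 near the background of both lines, and the call ended without i2PS replicate 2 (0.056) or i2PS replicate 3 (0.079).

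No whole chromosome of GRCm38.p6 stood apart from the rest (camera, 20 chromosomes, lowest adjusted p = 0.85). None passed at an unadjusted p under 0.05 either, whereas fry, which does not set a chromosome against other genes, called 7. The largest median shift from other genes was -0.11, on the X chromosome, where Tmem47 fell by 1.97 ± 0.14, Tceal5 fell by 1.90 ± 0.13 and Fgf13 fell by 1.76 ± 0.11. Within chromosome 12, however, neighbouring genes shifted together in opposite directions, as a search made after the data were examined showed. From Exd2 to Ifi27, 59 of 84 tested genes were higher in i2PS and 1 was lower, with a median of 0.55, and this stretch holds Itpk1. From Ppp4r4 to Dnah11, the last tested gene of the chromosome, 49 of 58 were lower and 0 were higher, with a median of -0.82, and this stretch holds the Dlk1-Dio3 genes. Across the alternatives the median of this stretch was -0.87 to -0.50, and that from Exd2 to Ifi27 was 0.36 to 0.67. The 143 tested genes before Exd2 had a median of -0.01. The ends of the stretches were placed where their medians best followed these same log2 differences. The counts and medians within them are therefore in part a product of that choice.

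**Figure D3:**
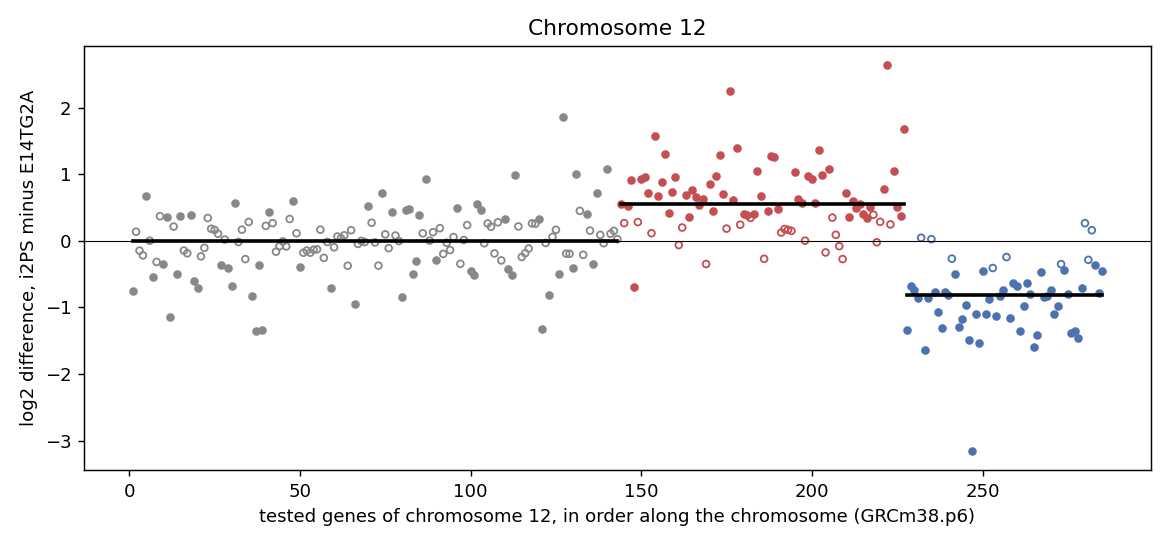
The log2 difference of each of the 285 tested genes of chromosome 12 in their order along the chromosome; filled points passed the adjusted p threshold of 0.05, open points did not, and black lines are the medians of 3 stretches. The medians are -0.01, 0.55 and -0.82.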

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

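In this part, the tests of feeder cells and of probes with strain variants were chosen only after the result was seen. Probes outside the gene comparison carried signal as well. Of 10396 probes without a single gene name, 1899 were tested, and 363 of them were higher and 308 lower in i2PS. This is a signal in data that the gene comparison leaves out, and the genes behind it were not analysed here.

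Of 18 tested targets of p53, 16 were lower in i2PS, and the call of the list (camera adjusted p = 5.5e-08) was lost with an estimated correlation (adjusted p = 0.19). Fibroblasts left from the feeders of E14TG2A are not excluded. Of 8 abundant matrix genes of fibroblasts, 0 were detected on all 3 E14TG2A arrays, but Col1a1 was detected on 2 of them. No fibroblast sample was measured that would show whether these probes respond. The dim array E14TG2A replicate 1 does not account for the fall, as the list's median was -1.02 without it. A strain variant under 1 probe would not by itself lower the other probes of a gene. In 12 of 12 genes that fell and had further kept probes all probes were lower. This count covers direction only, and variants under several probes of a gene are not excluded. Strain, tissue of origin and reprogramming history stay open as untested causes, and so does whether p53 activity differs between the lines. The p53 protein and the response to DNA damage would bear on this and were not analysed here.

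Of 15 tested genes of the fibroblast list, 9 were lower in i2PS, led by Acta2 and Tagln, and the call of the list (camera adjusted p = 0.0139) was lost with an estimated correlation (adjusted p = 0.25). The same matrix genes, 0 of 8 on all 3 E14TG2A arrays, do not exclude feeder cells, for the same reasons. Without E14TG2A replicate 1 the list's median was -0.87, which argues against the dim array. Strain variants under the probes cannot be told apart from a change in expression here, because only 3 genes that fell had further kept probes, although these were lower in 3 of 3. The cause of the fall is therefore left open, strain, tissue of origin and feeder cells included.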

How the results depend on the processing

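Alternatives for the shifted parts of chromosome 12 were chosen after seeing the data; all others were planned. No call of the 90 named genes changed direction in any alternative, though Klf4 (-0.14 to 0.42) and Tsix (-0.10 to 0.09), which did not pass in the main fit, fell on both sides of 0. Of the 1597 results of named genes, 1517 stayed on their side of the threshold, 74 lost the call, 32 of them with equal medians, and 6 gained it. No list call changed direction. The number of genes past the threshold was 634 with equal medians, which moved the median of all genes from 0.03 to 0.19, 1797 when tested against 1.2-fold and 2341 at an adjusted p under 0.01. At least 2-fold were 293 genes with normexp and 214 both without background correction and with the authors' table, where the signal left in dim probes narrows folds. Genes held within 2-fold were 3672 with equal medians, 17270 without a filter, where more genes were tested, and 3846 within 1.5-fold. Of the lists, 6 passed without background correction and with the authors' table, 4 among genes detected on all 6 arrays, 0 with an estimated correlation and 5 without E14TG2A replicate 1. Fry called 15 lists, adding pluripotency, ERK, glycolysis, cholangiocyte and cholesterol synthesis, and 7 chromosomes. Without the filter on dim probes, where undetected members enter, the medians shrank to -0.19 for primed epiblast, -0.12 for neuroectoderm, 0.06 for endothelial and 0.06 for germline genes. The cause was not tested for the other changes. With the replicate number as a block, 3613 genes and 8 lists passed, and the endothelial and neuroectoderm calls ended (camera adjusted p = 0.0510 each). Deviations from the line means correlated at r = 0.0089, -0.047 and 0.068 between arrays of the same number. Between arrays of different numbers they correlated at r from -0.077 to 0.063. No pairing by number was seen, but 3 arrays per line are too few to exclude it. Without each array in turn, 2763 to 4302 genes passed, 657 to 717 were at least 2-fold, 6711 to 7485 were held within 2-fold, 5 to 11 lists passed and the correlation difference was -0.0377 to -0.0326. Without the shifted parts of chromosome 12, 3672 genes and 10 lists passed. A slide block was not run. Dim signals limit genes detected in 1 line only to a lower bound.

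There are 10 splits of the 6 arrays, too few for a share under 0.05. The real split gave 3781 genes past the threshold, 675 of at least 2-fold, 6990 held within 2-fold, 10 lists and 0 chromosomes, and the highest of the other splits gave 0, 0, 7136, 4 and 0. As large a value came from 1, 1, 8, 1 and 10 of the splits.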

Other observations

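In this part, the test of neighbouring genes and that of strain variants along chromosome 12 were set before their results were seen, and so was the test of dim genes; the other tests were chosen afterwards. Among these, the tests of Rian against its neighbours and of Dlk1 replaced an earlier one whose reasoning failed once the neighbours were seen to fall, and the test of copies was restated against all genes after its value was known. Histone genes that are made during DNA replication were mostly lower in i2PS. Of 47 tested, 25 fell, 2 rose and 20 did not pass, with a median of -0.40. H2ac18 differed by -1.23 ± 0.20 and H4c9 by -0.81 ± 0.13. The group was picked because its genes fell, after a scan of 135 families of gene symbols, so that no p is given for it. Its members are near-identical copies that can share probe signal. Against all genes the median stayed below 0 under 4 other scalings, from -0.41 to -0.24.

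Neighbouring genes of chromosome 12 shifted together. In 422 runs of 20 neighbouring genes, the farthest median from all genes was -0.95, on chromosome 12, and none of 1000 shuffles of the genes gave a run as far (permutation p = 0.000999, the smallest they can give). The adjoining stretches shifted in opposite directions, so a single gained or lost segment would account for only 1 of the shifts. A candidate explanation is a gained segment beside a lost one in 1 of the lines. The fall was larger than the rise by 0.34 against all genes, and by 0.19 to 0.42 under 18 other settings, 2 of which lay under the lower bound of the test for a change of copies in i2PS. Because that test was restated after its value was known, it does not decide which line differs, and this is left open. The dim array does not account for it, since the distal median was -0.87 without E14TG2A replicate 1, and on single i2PS arrays it was -0.82, -0.83 and -0.85. Strain variants under the probes stay open: 14 of 16 distal genes that fell and had further kept probes had every probe lower, short of the bound set for excluding them, and DNA copy number was not analysed here. A gain or loss of a whole chromosome is not seen, with a largest chromosome median of -0.11.

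Rian and Meg3 lie in that distal stretch. With the main background correction, Rian fell at least 5.64-fold, farther than the median of its neighbours. Rian is expressed from the maternal allele, so its fall need not match that of its neighbours. The bound therefore does not exclude that a shared change lowered both. For Meg3, at least 1.72-fold lower, the bound leaves open even whether it fell farther than its neighbours. Across the alternatives Rian lay at -3.30 to -1.47 and the median of the distal genes at -0.87 to -0.50, so the size of the gap depends on the processing. After normalization, 1350 genes of the same mean level had a median of 0.024, so dim genes in general did not fall. Quantile normalization itself evens out such shifts, so this does not decide whether the normalization had a part. Dlk1 lay -0.16 from the median of the other distal genes, within the bound set for a loss of the maternally expressed genes beyond their neighbours' shift. Because Dlk1 is expressed from the paternal allele, it need not follow its neighbours either, so this test does not decide. Such a loss stays an untested candidate explanation. Strain variants cannot be told apart from such a loss, because 0 further probes of Rian or Meg3 were detected on all 3 E14TG2A arrays.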
